A study of Mus musculus with 12 samples.

How the data were processed

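Gene expression was measured on Illumina mouse bead arrays in 12 samples: 4 of ITNK cells (induced T-to-natural-killer cells, which arise when T-lineage cells lose the transcription factor Bcl11b), 4 of DN3 thymocytes (CD4- and CD8-negative T cell precursors at the stage of T cell receptor beta rearrangement) and 4 of LAK cells (lymphokine-activated killers, natural killer cells expanded with IL-2). The labels carry the same treatment and growth text on all 12 samples and do not say which steps apply to which group, so whether DN3 and LAK cells were treated, and how LAK cells were grown beyond their IL-2 expansion, stays unknown. The strain labels read C57B6 for ITNK, C57B7 for DN3 and C57B8 for LAK. This run of numbers may come from filling down a single strain name, so the labels were not used, and whether strain differed between groups stays unknown. Per that text, cells of mice with loxP-flanked Bcl11b and a tamoxifen-inducible Cre recombinase were given 1 µM 4-hydroxytamoxifen for 48 h. Sorted DN3 thymocytes were then cultured on OP9-DL1, a bone marrow stromal line that presents the Notch ligand Delta-like 1, with 100 ng/ml IL-2, and cells were collected 14 days after the treatment. The same text describes a further expansion for 6 to 9 days in 1000 U/ml IL-2 for splenic ITNK cells, and no sample here is labelled splenic. The labels do not say whether the RNA of the DN3 arrays came from freshly sorted or cultured cells, nor whether the arrays of a group came from separate animals or cultures. RNA was amplified to biotin-labelled cRNA with the Ambion MessageAmp kit, per the labels. The scanner software was not given in the sources used here.

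The scanner table that the authors deposited holds, per the file headers, a mean bead intensity per probe and array on a linear scale, with no normalization between arrays and no background subtraction. Beside it the authors deposited a detection value for each probe and array, a fraction from 0 to 1 that gives the share of negative control beads the probe exceeds, so that 1 minus this value is the detection p-value. A second deposited table holds the authors' processed values on a log2 scale, with a median of 6.16 or 6.17 on each array. Set against each array's own signals these values were not centred, and the array of ITNK 1 appeared to be their reference. The method that made them stays unknown, and their lowest values do not follow the order of the signals, so they served only as an alternative.

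From the intensities, background was corrected by a normal-exponential fit whose background mean and spread came from the detection values. An offset of 16 was added and the arrays were quantile normalized on the log2 scale (the neqc function of limma 3.58.1 in R 4.3.3). Of 45281 probes 7 held no values. Among the other 45274, the platform annotation gave 1 gene symbol to 34880, several to 18 and none to 10376, and the Entrez numbers of 34807 of its 34903 annotated probes matched the gene table used to update symbols. A probe was kept when its detection p was under 0.01 on at least 4 of the 12 arrays. This left 13571 probes, of which 1804 had no single symbol and stayed out of the gene counts. Each gene was represented by its probe with the highest mean over all arrays, which gave 8100 genes. Of these, 2688 had more than 1 detected probe, and their probes were called in opposite directions in 40 genes for ITNK against DN3, 15 for ITNK against LAK and 110 for LAK against DN3. Members of the Klra, Klrb1, Gzmd to Gzmg and Bcl2a1 families are near-identical copies that can share probe signal, so their values are uncertain as to which copy they measure.

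The 3 groups were compared in 1 linear model in limma over all 12 arrays, with moderated 2-sided tests and Benjamini-Hochberg adjustment over the 8100 genes in each comparison. A gene passed at an adjusted p under 0.05, and the number that also differed at least 2-fold is given beside it. A gene detected on no array of the dimmer group has only a bound there, written as "at least N-fold". The brighter group's mean is set against the dimmer group's mean of, per array, the lowest normalized value of a detected probe or the gene's own value if that was higher. No fold is given where neither group was detected. The 12 arrays lay on 2 slides. Slide 1 held all LAK arrays with ITNK 1 and 2, and slide 2 held all DN3 arrays with ITNK 3 and 4. With slide as a fixed block, ITNK against DN3 rests on the arrays of slide 2 and ITNK against LAK on those of slide 1, so the blocked differences equal the within-slide ones and only their p-values differ. LAK against DN3 has no value within a slide.

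A position of ITNK between DN3 and LAK was computed for each gene at least 2-fold different between LAK and DN3, as the ITNK minus DN3 difference over the LAK minus DN3 difference, and summarised as the median over genes in each ITNK array. The 26 gene lists covered natural killer receptors, the Ly49 family, cytotoxic granules, natural killer and T lineage transcription factors, T lineage surface and signalling genes, recombination genes, the Notch pathway, cytokine receptors, cytokines, homing, cell cycle, glycolysis, cholesterol synthesis, interferon response, MHC class II, p53 targets, stress genes, ribosomal proteins, other innate lymphoid types and 6 groups of markers of other cells (stroma, B cells, myeloid cells, mast cells, erythroid cells, and gamma-delta and natural killer T cells). The 24 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with a correlation estimated from the residuals and fry, which tests whether the genes of a list move, on balance, in 1 direction.

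Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for the tests of a mixture, of the stromal transcripts and of the Bcl11b probes, which were chosen after the result was seen. The rule names Bcl11b; a set of key natural killer and T cell genes; the 10 genes with the largest rise and the 10 with the largest fall in each ITNK comparison, and 5 of each for LAK against DN3; up to 4 members of each list with the largest difference; and the 8 highest and 8 lowest genes that lay apart from both other groups. Genes named for a large rise or fall had to pass the test, be detected on all arrays of the higher group, have no array of one group within the range of the other, and carry a symbol that is not a clone or predicted-gene name. Where 5 or fewer members of a list rose, fell or did not pass, those outside the rule are named as well, and these were chosen after their values were seen. Of the key genes, Nfil3, Gzma and Tcf7 had no probe named in the annotation, and Ncr1, Zfp105, Zbtb16 and Gzmb were detected on 0 of 12 arrays, the LAK arrays included, so nothing is reported on them.

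The steps were tested on simulated data for ITNK against DN3 with 9168 genes. All 50 genes changed 2-fold were called, as were all 50 changed 4-fold and all 50 changed 8-fold, against 32 of 50 changed 1.5-fold. The median estimates of the absolute log2 difference were 0.92, 1.76, 2.72 and 0.49, below the true values of 1, 2, 3 and 0.58. Of 8568 unchanged genes 25 were called, a simulated position of 0.6 was found as 0.610, and none of the other 24 lists was called. The changed genes were drawn from those of middle level in DN3, with as many rises as falls, and most genes stayed unchanged. Recovery of dim genes, and normalization where a large share of genes changes, were therefore not tested. The alternatives tried were no background correction (signals under 16 raised to 16), a normal-exponential fit to all probes with an offset of 50, median scaling in place of quantiles, the authors' processed values, no filter, a detection p under 0.05, detection on all 12 arrays, slide as a fixed or a random block, single slides, replicate number as a block, only the 8 arrays compared, a trended robust variance, array weights, the mean of a gene's probes, every probe by itself, and each array left out in turn. Every column of the files was assigned to a sample, and the number of arrays limits the precision of each value.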

Results

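Genome-wide expression was measured in 3 lymphoid populations of mouse origin with 4 arrays each: ITNK cells made in vitro from DN3 thymocytes by deletion of Bcl11b, DN3 thymocytes as the parental T cell precursors, and LAK cells as a natural killer reference. The design asks how far T cell precursors resemble natural killer cells after deletion of Bcl11b, and which T cell transcripts they keep. Each array detected 11814 to 13141 of 45274 probes (26.1% to 29.0%), with group means of 12273.5 ± 269 for DN3, 12578.8 ± 399.7 for ITNK and 12245 ± 411 for LAK (SD, n = 4 arrays). The median signal was 71.4 to 75.3 on slide 1 and 58.9 to 63.3 on slide 2. Since the labels do not say that the arrays of a group came from separate animals or cultures, the p-values measure only the spread between these samples, which may be technical.

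Replicate arrays were close to each other, and ITNK stood between the other 2 groups. The median correlation across genes, which are not independent replicates, was 0.987 within DN3, 0.986 within ITNK and 0.985 within LAK. Between groups it was 0.912 for DN3 with ITNK, 0.921 for ITNK with LAK and 0.836 for DN3 with LAK. The first principal component (67.1% of the variance) placed LAK arrays at -53.6 to -44.4, ITNK arrays at -9.33 to 2.81 and DN3 arrays at 47.9 to 54.0. The second (19.4%) set ITNK, at 30.5 to 31.5, apart from all LAK and DN3 arrays, at -19.0 to -11.2.

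**Figure D1:**
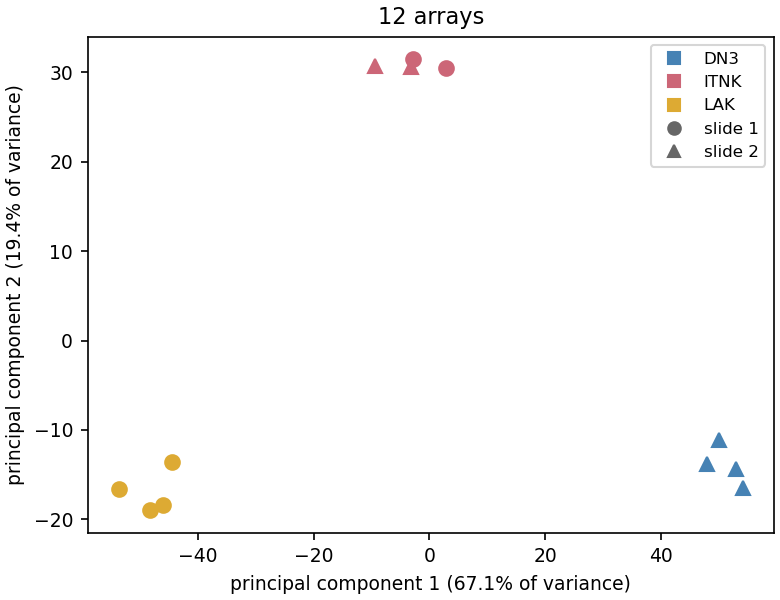
Principal components of the 12 arrays over the 8100 tested genes, with the first component (67.1% of the variance) on the x axis and the second (19.4%) on the y axis; each symbol is 1 array, coloured by group, with circles for slide 1 and triangles for slide 2. The 4 ITNK arrays, from both slides, lie together between LAK and DN3 on the first component and above both on the second.

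Bcl11b, the transcription factor that commits thymocytes to the T lineage and the gene deleted in this design, was at 11.77 ± 0.24 in DN3, 8.59 ± 0.35 in ITNK and 5.76 ± 0.36 in LAK (log2, SD, n = 4 arrays each) by its brightest probe. It fell by 3.18 in ITNK against DN3 (SE 0.20, adjusted p = 2.24e-08) and stayed 2.83 above LAK (adjusted p = 7.51e-08). With slide as a block, and within single slides, these differences were -3.39 and 3.03. Between LAK and DN3 the difference was -6.01 (adjusted p = 1.39e-11), or -6.42 with slide as a block. Of the other 3 probes, 1 was detected on 0 arrays and the remaining ones fell less in ITNK, by 1.17 and 1.03 (SE 0.12 each), and neither was detected in LAK. As a share of the DN3 signal, the ITNK signal that remained was 10.8% by the brightest probe and 43.2% and 38.9% by the others. Where each probe lies relative to the deleted part of the gene is not in the labels, and a probe outside it does not check the deletion.

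**Figure D2:**
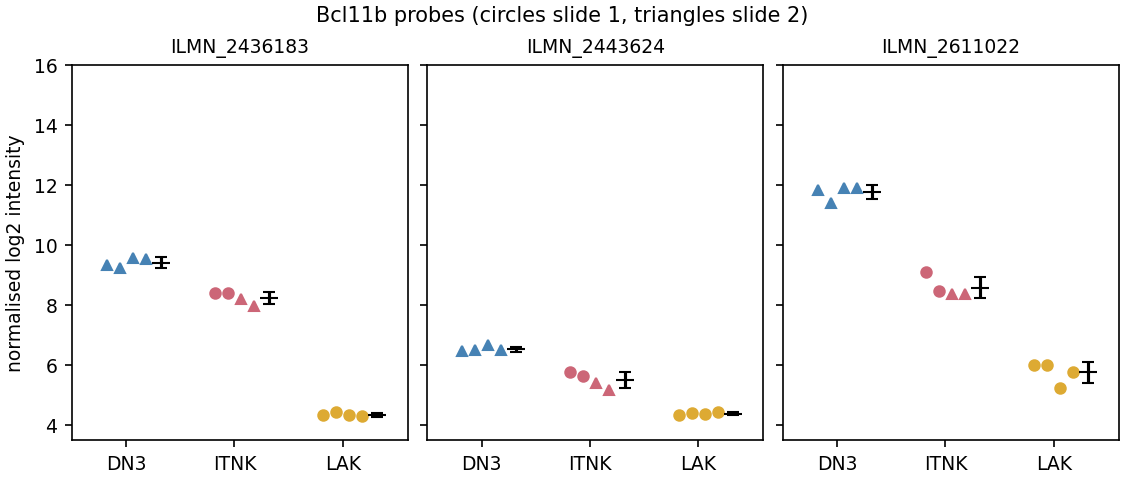
Level of the 3 detected Bcl11b probes (y axis, normalized log2 signal) in the 4 arrays of each group; points are arrays, and bars give the mean ± SD. The brightest probe stands at 11.77 in DN3, 8.59 in ITNK and 5.76 in LAK.

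In ITNK against DN3 several natural killer genes rose and several genes of T cells and lymphoid precursors fell. Zbtb32, a zinc finger repressor expressed in activated natural killer cells, went from 4.45 ± 0.21 and no detection in DN3 to 11.31 ± 0.33 in ITNK (SD, n = 4 each; at least 113-fold, adjusted p = 3.26e-11). The activating adaptors Fcer1g and Tyrobp, which couple natural killer receptors to intracellular kinases, rose by 5.93 (SE 0.27, adjusted p = 1.31e-09) and at least 35.6-fold (adjusted p = 3.36e-11). Klrd1, the CD94 chain of the CD94-NKG2 receptors, rose by 4.42 (SE 0.20, adjusted p = 1.32e-09), and Nkg7, a cytotoxic granule membrane protein, by 4.24 (SE 0.19). Cd6, a T cell costimulatory receptor, fell by 3.07 (SE 0.16, adjusted p = 3.92e-09), and Ly6d, a surface marker of early lymphoid precursors, fell by 3.10 (SE 0.15, adjusted p = 2.86e-09).

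Of 8100 genes 4184 passed in ITNK against DN3, 1903 higher and 2281 lower, and 1055 of them differed at least 2-fold (597 higher, 458 lower). That number was 561 without background correction, 559 with a background fit to all probes, 525 with the authors' values, 537 with probes detected on all 12 arrays and 1646 counting every probe, where 6745 passed. In 3874 genes (47.8%) no ITNK array lay within the DN3 range, against 2.86% by chance. The slide block left 3595 genes past the test (1138 at least 2-fold), and 3666 (1136) within slide 2. The other largest rises were those of Upp1 (uridine phosphorylase, 6.77), the water and glycerol channel Aqp9 (5.36), the actin-binding proteins Avil (5.23) and Scin (4.98), the chemokine Xcl1 (4.94) and Lta (lymphotoxin alpha, 4.49). The other largest falls were those of Cox6a2 (-3.38), H2-Bl (-3.05), Gldc (-2.98), Slc16a5 (-2.88), Pld4 (-2.79) and Ccl9 (-2.68), and Prelp was at least 9.28-fold lower.

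Among 20 measured natural killer receptors and adaptors 15 rose, Slamf6 fell by 1.74 and Klrb1a, Klrb1b, Klri2 and Klrg1 did not pass (16 rose and 1 fell adjusted over the list alone). Their median log2 difference was 1.87, also with genes at their bound (camera, adjusted p = 9.2e-08; adjusted p = 0.113 with an estimated correlation). Klrk1 (NKG2D) rose at least 3.66-fold, Klrb1c (NK1.1) at least 2.25-fold and Cd160 by 3.67. Klrg1, a receptor of mature cells, was detected on no DN3 array and differed by 0.38 from that background level (adjusted p = 0.19; within slide 2 0.0211). Klrb1b (0.40) passed with slide as a block (0.75, adjusted p = 1.06e-04) and without ITNK 1 or ITNK 2 (adjusted p = 0.0279 and 0.00748). In the Ly49 family of MHC class I receptors none of 7 measured members passed (0 also adjusted over the list alone; median -0.05, or -0.34 with bounds, adjusted p = 0.778), and 0 of the 7 were at an unadjusted p under 0.05. None of the 7 was detected on any ITNK array, and 5 were not detected on any DN3 array either. For these 5 both groups were at background, so the test could show no difference. Of 18 cytotoxic granule genes and death ligands 10 rose and 0 fell (the same counts adjusted over the list alone). The median was 0.73, or 0.94 with bounds (adjusted p = 4.8e-04; adjusted p = 0.213 with an estimated correlation). Ctsw, a protease of killer lymphocytes, rose by 3.29, Stx11, a granule docking protein, by 2.54 and Fasl, the ligand of the death receptor Fas, at least 3.52-fold. Gzmd (1.59, adjusted p = 0.0764) passed with slide as a block (2.77, adjusted p = 0.00682; within slide 2 0.0286) and without ITNK 2 or DN3 2 (2.05 and 2.26, adjusted p = 0.0333 and 0.00909). Gzme, detected on 1 ITNK array and on 0 DN3 arrays, differed by 0.39 (adjusted p = 0.232) and passed with slide as a block (0.88, adjusted p = 0.0095; within slide 2 0.0103). Prf1 (perforin) rose by 0.77 (SE 0.27, adjusted p = 0.0303; 1.253 with slide as a block), and it did not pass without DN3 1, DN3 2, DN3 4, ITNK 3 or ITNK 4 (0.67, 0.77, 0.80, 0.76 and 0.45; adjusted p = 0.0818, 0.0536, 0.05, 0.0578 and 0.0785). With slide as a block the medians of these 3 lists were 2.04, 0.03 and 1.04 (adjusted p = 1.58e-08, 0.972 and 4.8e-05; within slide 2 1.29e-08, 0.977 and 9.43e-05).

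Of 14 measured natural killer transcription factors 6 rose, Ets1 (-1.88), Id3 (-1.60) and Ikzf2 (-1.05) fell, and Zeb2, Irf2, Stat4, Tox and Rora did not pass (7 and 3 adjusted over the list alone). Id2, which antagonises E proteins in innate lymphocytes, rose by 2.65 (SE 0.14, adjusted p = 5.08e-09), Hhex at least 5.66-fold, Eomes at least 2.57-fold and Tbx21 (T-bet) at least 2.00-fold. Stat4 (0.48) passed with slide as a block (adjusted p = 0.0488) and without LAK 2, LAK 3 or DN3 3 (adjusted p = 0.0347, 0.0102 and 0.0385). Tox (0.36) passed within slide 2 (adjusted p = 0.0224). The list as a whole did not pass (median 0.45, adjusted p = 0.0815), nor did it with slide as a block (0.52, adjusted p = 0.0788), but it did within slide 2 (adjusted p = 0.0470). Of 13 cytokines and chemokines 10 rose, Ccl9 and Il16 (-0.35) fell and Ltb did not pass (11 and 2 adjusted over the list alone; median 2.06, adjusted p = 6.99e-05; adjusted p = 0.126 with an estimated correlation). Ifng, the hallmark natural killer cytokine, rose at least 11.4-fold, Ccl4 by 3.19 and Ccl3 at least 4.16-fold. The call of Il16 was lost without ITNK 1, ITNK 3, ITNK 4, DN3 2, DN3 3 or DN3 4 (adjusted p from 0.061 to 0.112). Ltb (0.54) passed without LAK 3 or DN3 3 (adjusted p = 0.0487 and 0.00223). Of 23 cytokine receptors and IL-2 response genes 11 rose and Il7r (-2.30), Socs3 (-0.93), Ifngr1 (-0.89) and Stat5a (-0.66) fell (the same adjusted over the list alone; median 0.21, adjusted p = 0.0501). Il18r1 rose by 3.40, the IL-2 receptor chain Il2rb at least 3.11-fold, and Cish and Pim2, which IL-2 signalling induces, by 2.09 and 2.05, while Il2ra differed by 0.08 (adjusted p = 0.75). This list passed without DN3 3, ITNK 3, ITNK 4, LAK 1, LAK 3 or LAK 4 (adjusted p = 0.0451, 0.0337, 0.0481, 0.0468, 0.0448 and 0.0497) and not with slide as a block (0.10, adjusted p = 0.0998; within slide 2 0.121). The blocked median of the cytokine list was 2.04 (adjusted p = 4.8e-05; within slide 2 9.43e-05).

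Of 19 homing and adhesion genes 10 rose, and Cxcr4 (-1.42) and Cd47 (-0.86) fell (the same adjusted over the list alone). The median was 0.87, or 0.85 with bounds (adjusted p = 0.00333; adjusted p = 0.188 with an estimated correlation), and 0.80 with slide as a block (adjusted p = 0.00311; within slide 2 0.0033). Cd44 rose by 2.64, the chemokine receptors Cxcr3 by 2.28 and Cx3cr1 at least 5.15-fold, and the early activation marker Cd69 by 2.25. Itgal (0.31, adjusted p = 0.249) passed with slide as a block (0.76, adjusted p = 0.00218; within slide 2 0.00934) and without ITNK 1 (0.51, adjusted p = 0.0437). The median of this list moved to 0.36 without ITNK 1 and 0.32 without ITNK 2, and to 0.24 without ITNK 3 and 0.20 without ITNK 4, where the list no longer passed (adjusted p = 0.0511 and 0.0567).

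On the T cell side, 11 of 19 measured T lineage surface and signalling genes fell and 2, the costimulatory receptors Icos (1.49) and Cd28 (0.81), rose (12 and 2 adjusted over the list alone). The median was -0.85 (adjusted p = 0.00998; adjusted p = 0.245 with an estimated correlation). Cd2 (-1.97), Cd8b1 (-1.93) and Cd3d (-1.26) were among those that fell. The other CD3 chains, signalling subunits of the T cell receptor, were at 11.93 ± 0.07 in DN3 and 11.40 ± 0.14 in ITNK for Cd3e (-0.52, adjusted p = 0.123) and 11.73 ± 0.13 and 11.32 ± 0.20 for Cd3g (-0.41, adjusted p = 0.0534). Neither passed in the model of 12 arrays, nor with slide as a block (-0.61 and -0.49, adjusted p = 0.171 and 0.0766), but both did within slide 2 alone (adjusted p = 0.00328 and 0.0169). Cd3e also passed without LAK 2 (adjusted p = 0.0356), and Cd3g without ITNK 2, LAK 1, LAK 3 or LAK 4 (adjusted p = 0.0371, 0.0344, 0.0473 and 0.0264). Of 16 T lineage transcription factors 13 fell, Hhex rose and Ikzf3 and Mef2c did not pass (the same adjusted over the list alone; median -0.81, or -0.82 with bounds, adjusted p = 4.22e-04; adjusted p = 0.188 with an estimated correlation). Sox4 (-2.26), Gfi1 (-1.96), Ets2 (-1.66) and Gata3, a regulator of early thymocytes (-0.79), fell.

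Of 8 Notch pathway genes 5 fell, Maml1 and Myc did not pass and Nrarp, a feedback inhibitor, rose by 0.88 (the same adjusted over the list alone; median -1.13, or -1.12 with bounds, adjusted p = 0.0253; adjusted p = 0.214 with an estimated correlation). Notch3 (-2.58), the Notch target Dtx1 (-2.28), Notch1 (-1.45) and Hes1 (-0.84; -0.69 and adjusted p = 0.108 with slide as a block) fell, and Ptcra, the pre-T cell receptor alpha chain, was at least 2.64-fold lower. This list did not pass without DN3 1, DN3 2 or DN3 3 (medians -0.77, -1.08 and -0.75; adjusted p = 0.0896, 0.0705 and 0.0614). Of 9 recombination and pre-T cell receptor genes 6 fell, Slc6a13 (at least 2.56-fold) and Cpa3 (0.96) rose and Il2ra did not pass (the same adjusted over the list alone). The call of Cpa3, a protease also made by mast cells, was lost with slide as a block (0.82, adjusted p = 0.117) and without DN3 4, ITNK 1 or ITNK 3 (adjusted p = 0.0706, 0.0724 and 0.0615). Arpp21 (-2.04), the terminal transferase Dntt (-1.68) and the recombinase Rag1 (-1.09) fell. The median of -1.09 did not pass (adjusted p = 0.0575), but it did with slide as a block (-1.29, adjusted p = 0.0189; within slide 2 0.0450) and without ITNK 1 (-1.31, adjusted p = 0.0278). The blocked medians were -0.87 for the surface genes, -0.91 for the transcription factors and -0.99 for the Notch pathway (adjusted p = 0.00574, 2.31e-04 and 0.0317; within slide 2 0.00111, 1.67e-04 and 0.0401).

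Stromal transcripts moved in the same direction as these T cell lists. Of 15 measured stromal markers 10 fell, Fstl1, Mgp and Igfbp7 did not pass and Timp3 (2.21) and Ccn2 (2.19) rose (the same adjusted over the list alone). Cxcl12, a stromal chemokine, was at 9.81 ± 0.98 in DN3 and 7.84 ± 0.65 in ITNK, and Bgn, a matrix proteoglycan, at 10.51 ± 0.79 and 8.99 ± 0.28. Fstl1 and Igfbp7 passed without DN3 2 (-0.76 and -0.47, adjusted p = 0.0381 and 0.0263). The median was -1.16 (adjusted p = 0.0340; adjusted p = 0.581 with an estimated correlation). Under the slide block it was -1.27 (adjusted p = 0.0317), and the list did not pass within slide 2 (adjusted p = 0.0589), nor without ITNK 2 or ITNK 4 (adjusted p = 0.0536 and 0.0687). Of other cells' markers, 0 of 5 myeloid genes passed in limma (median -0.03, or -0.11 with bounds, adjusted p = 0.902), and 0 of the 5 were at an unadjusted p under 0.05. Cpa3 and Kit rose and Cma1 and Hdc did not pass among 4 mast cell genes (median 0.37, or 0.96 with bounds, adjusted p = 0.501), and the B cell gene Cd79b fell by 0.50. The erythroid gene Hba-a1 rose by 2.91. Among 3 genes of gamma-delta and natural killer T cells, Cd163l1 rose by 0.85, Blk fell by 1.16 and Trgv4 differed by -0.26 (adjusted p = 0.459, within slide 2 -0.46 and 0.00893; list median -0.26, adjusted p = 0.782). The counts of these small lists were the same adjusted over the list alone, and their blocked medians were 0.01, 0.36 and -0.46 (adjusted p = 0.902, 0.459 and 0.659; within slide 2 0.977, 0.524 and 0.542).

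**Figure D3:**
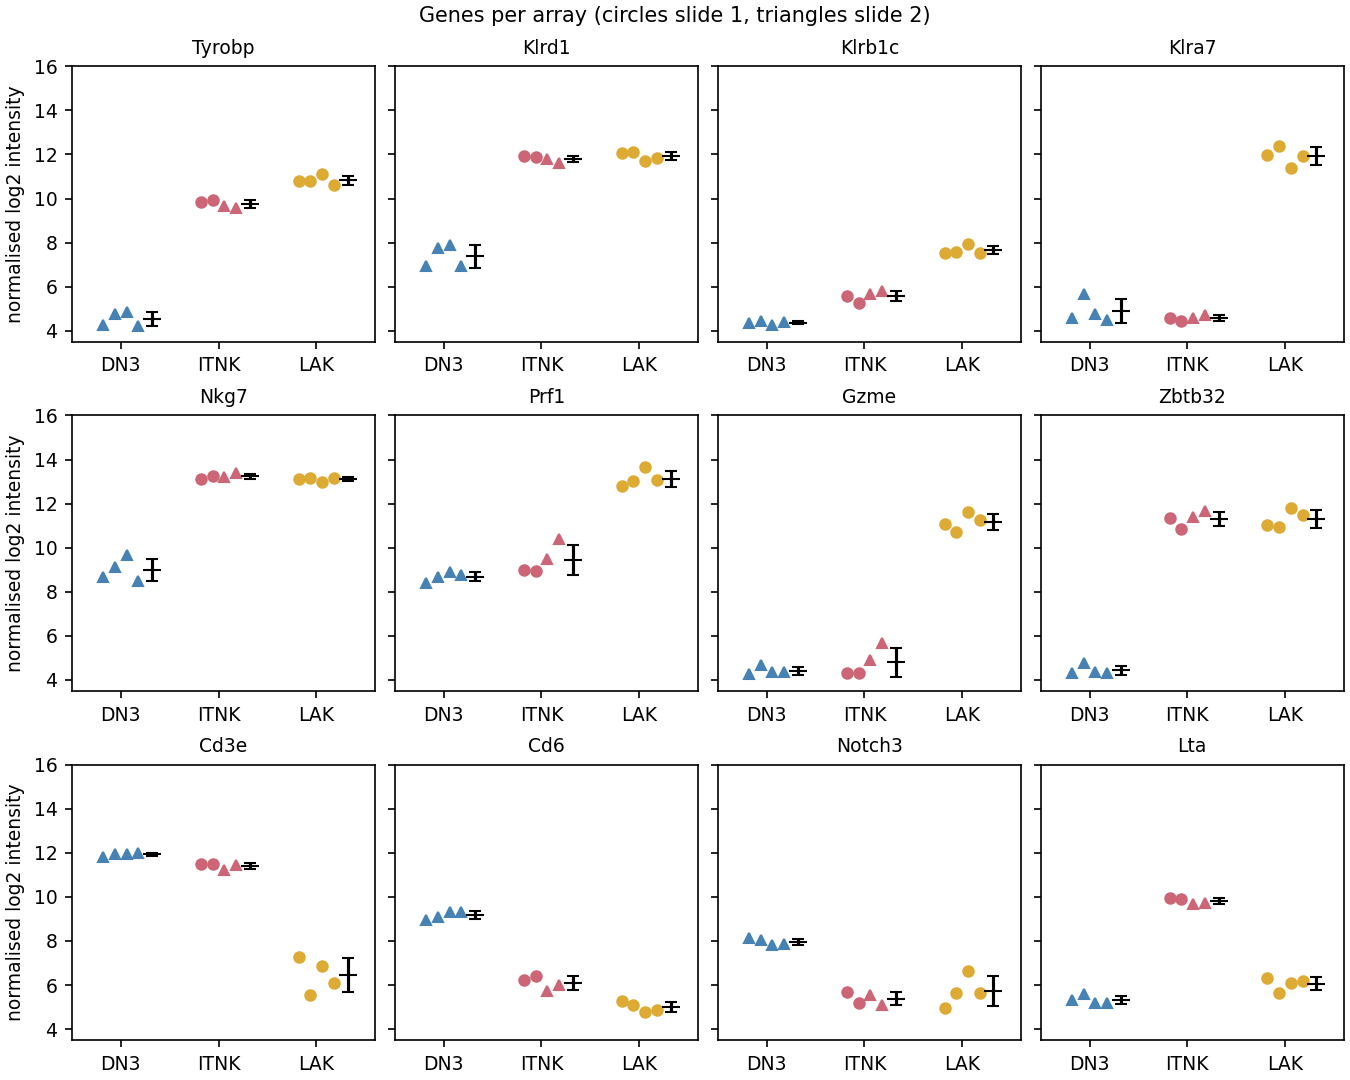
Levels of 12 named genes (y axis, normalized log2 signal) in the 4 arrays of DN3, ITNK and LAK; points are arrays, and bars give the mean ± SD. Tyrobp, Klrd1, Nkg7 and Zbtb32 are high in ITNK and LAK, Klra7 and Gzme in LAK alone, Cd3e in DN3 and ITNK, Cd6 and Notch3 in DN3, and Lta in ITNK.

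Compared with LAK cells, ITNK cells had less signal for the 7 measured Ly49 receptors and several granzymes and more for T cell receptor components. Klra7 (Ly49G) was detected on no ITNK array and lay at 11.92 ± 0.42 in LAK (SD, n = 4; at least 162-fold lower, adjusted p = 4.63e-11). Gzme, a granzyme of activated killer cells, was at 4.81 ± 0.65 in ITNK and 11.16 ± 0.37 in LAK (-6.36, SE 0.26, adjusted p = 4.12e-10). Cd163l1, a scavenger receptor found on gamma-delta T cells, was higher by 6.58 (SE 0.15, adjusted p = 1.87e-12), and Cd3e by 4.96 (SE 0.27, adjusted p = 6.45e-09). Trat1, a T cell receptor interacting adaptor, was at least 62.7-fold higher (adjusted p = 1.76e-14), and Itgae (CD103), an integrin of intraepithelial lymphocytes, was higher by 6.06 (SE 0.28).

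In this comparison 2727 genes passed, 1458 higher and 1269 lower in ITNK, and 722 differed at least 2-fold (444 higher, 278 lower). In the first 4 settings given for ITNK against DN3 that number was 393, 388, 378 and 269. With probes detected on all 12 arrays 1787 passed, and 4307 counting every probe. In 2574 genes (31.8%) the arrays of the groups did not overlap, against 2.86% by chance. The slide block left 2246 genes past the test (799 at least 2-fold), and 1857 (795) within slide 1. Other genes with the largest differences were Pdlim4 (at least 80.3-fold higher), Igfbp4 (at least 50.5-fold), Myl10 (5.86), Fam169b (5.17), Trgv4 (4.92), a gamma chain variable segment, and Drc1 (at least 29.0-fold). Lower in ITNK were Klra4 (at least 79.1-fold), Gzmd (-6.13; -7.31 with slide as a block), Klra3 (at least 61.2-fold), Gzmg (at least 56.8-fold), Ctsg (at least 49.1-fold), Speer3 (-5.31), Speer1 (at least 32.0-fold) and Cd55 (at least 31.8-fold).

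All 7 measured Ly49 genes were lower in ITNK (median -3.94, also with bounds, adjusted p = 3.36e-12). Of 20 natural killer receptors 12 were lower and 2, Cd160 (1.38) and Slamf6 (at least 1.44-fold), higher (14 and 3 adjusted over the list alone; median -1.10, adjusted p = 1.23e-06). Klrg1 (-4.87), Klrb1b (-3.13) and Klre1 (-3.02) were among the lower ones, whereas Klrd1 differed by -0.12 (adjusted p = 0.69). Klrb1c (-2.06), Klrk1 (-1.14) and Tyrobp (-1.07) were also lower. The call of Slamf6 was lost with slide as a block (adjusted p = 0.0526) and without LAK 1, LAK 2, ITNK 1 or ITNK 2 (adjusted p = 0.0549, 0.0645, 0.0504 and 0.0795). Of 18 cytotoxic genes 11 were lower and 1, Tnfsf10 (0.60; 0.48 and adjusted p = 0.0924 with slide as a block), higher (the same adjusted over the list alone; median -0.60, adjusted p = 3.2e-05; adjusted p = 0.134 with an estimated correlation). Prf1 lay at 9.45 ± 0.68 against 13.13 ± 0.36 in LAK (-3.68, SE 0.27, adjusted p = 1.47e-07), while Nkg7 differed by 0.11 (adjusted p = 0.691). The median of the cytotoxic list was between -0.40 and -0.33 without any 1 of the LAK arrays (-0.33, -0.40, -0.33 and -0.37 without LAK 1 to LAK 4), and the list passed each time. With slide as a block the 3 medians were -3.999, -1.20 and -0.87 (adjusted p = 7.61e-12, 3.9e-07 and 4.46e-06; within slide 1 3.14e-10, 8.45e-07 and 5.9e-06).

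Of 19 T lineage surface genes 15 were higher in ITNK, 0 lower and Zap70, Ubash3a, Icos and Lcp2 did not pass (the same adjusted over the list alone; median 1.08, or 1.09 with bounds, adjusted p = 1.8e-10), among them Cd3g (4.41), Cd3d (3.82) and Cd8b1 (3.81). Of 9 recombination genes 8 were higher and Ptcra, detected in neither group, did not pass (the same adjusted over the list alone; median 1.18, or 1.42 with bounds, adjusted p = 1.42e-06). Arpp21 was at least 19.0-fold higher, Dntt at least 6.26-fold and Ly6d at least 3.17-fold. All 3 gamma-delta and natural killer T cell genes were higher (median 4.92, adjusted p = 9.07e-06). The 3 blocked medians were 1.19, 1.61 and 5.12 (adjusted p = 5.16e-11, 4.87e-07 and 7.77e-06; within slide 1 1.63e-09, 8.45e-07 and 3.25e-05). Stromal markers moved with these T cell genes: 14 of 15 were higher in ITNK and Col1a1 did not pass (the same adjusted over the list alone; median 1.62, or 1.61 with bounds, adjusted p = 1.84e-08; adjusted p = 0.157 with an estimated correlation; 1.77 with slide as a block, adjusted p = 4.61e-08; within slide 1 3.38e-13), and none of the 15 was detected in LAK. Fstl1 did not pass with slide as a block (0.88, adjusted p = 0.116), although it did within slide 1, nor without LAK 2, LAK 3, LAK 4, ITNK 1 or ITNK 3 (adjusted p from 0.0509 to 0.0859). The B cell gene Cd79b was at least 3.86-fold higher and Hba-a1 higher by 3.52. Of the myeloid genes Ctsg and Cd14 (at least 2.56-fold) were lower and Lgmn (0.56) higher, and of the mast cell genes Cma1 (at least 2.21-fold) was lower and Cpa3 (3.06) higher (list medians -0.19 and 0.22, adjusted p = 0.346 and 0.617; 0.002 and 0.23 with slide as a block, adjusted p = 0.382 and 0.649; within slide 1 0.497 and 0.528). Hdc, the 1 other mast cell gene that was higher (at least 1.33-fold, adjusted p = 0.0423), did not pass with slide as a block (0.29, adjusted p = 0.244), nor without LAK 1, LAK 2, LAK 3, ITNK 2, ITNK 3, ITNK 4, DN3 2 or DN3 4 (adjusted p = 0.0698, 0.0894, 0.0881, 0.0938, 0.0548, 0.127, 0.0516 and 0.0538). The call of Lgmn was lost within slide 1 (0.57, adjusted p = 0.0673).

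The transcription factor lists did not pass. Of 14 natural killer factors 3 were higher, Tox (1.62), Ikzf2 (at least 2.88-fold) and Id3 (at least 2.28-fold), and 5 lower, Irf8 (-3.48), Tbx21 (-1.63), Eomes (-1.31), Hhex (-1.03) and Zeb2 (at least 1.46-fold), with the same counts adjusted over the list alone (median -0.15, adjusted p = 0.438). Id2 differed by -0.06 (adjusted p = 0.776). Without LAK 2 Zeb2 did not pass (adjusted p = 0.0513). Of 16 T lineage factors 10 were higher, among them Sox4 (at least 7.70-fold), and 4 lower, Mef2c (at least 6.45-fold), Gfi1 (-1.67), Ikzf3 (-1.40) and Hhex, while Foxo1 and Foxp1 did not pass (10 and 5 adjusted over the list alone; median 0.58, adjusted p = 0.105). That list passed without LAK 1, LAK 2, LAK 3 or LAK 4 (adjusted p = 0.0237, 0.0170, 0.0216 and 0.0309). Foxo1 passed without LAK 4 (-0.35, adjusted p = 0.0451). Of 8 Notch genes Dtx1 (at least 3.41-fold) and Notch1 (0.68) were higher (the same adjusted over the list alone; median 0.13, or 0.16 with bounds, adjusted p = 0.413), and Notch3 differed by -0.34 (adjusted p = 0.349). Of 23 cytokine receptor genes 11 were higher, among them Socs3 (2.10), Il2ra (1.17) and Il7r (1.17), and 5 lower, Il12rb2 (-1.17), Il10ra (-0.96), Il2rb (-0.90), Jak3 (-0.85) and Il12rb1 (-0.61) (12 and 6 adjusted over the list alone; median 0.46, adjusted p = 0.0933). Il12rb1 did not pass without LAK 3, ITNK 1 or ITNK 2 (adjusted p = 0.0516, 0.0532 and 0.0513). Of 13 cytokines Lta (3.76), Ltb (1.66) and Tnf (1.31) were higher, Ccl3 (-3.44), Ccl4 (-3.27), Ccl5 (-1.54), Ccl9 (-1.22) and Tgfb1 (-0.52) lower, and Ifng (0.38, adjusted p = 0.215), Csf2, Xcl1, Il16 and Flt3l did not pass, with the same counts adjusted over the list alone (median 0.14, mean -0.17, adjusted p = 0.957). The call of Ccl5 was lost with slide as a block (-1.46, adjusted p = 0.0968) and without LAK 2, LAK 4, ITNK 1 or ITNK 3 (adjusted p = 0.0719, 0.0713, 0.0511 and 0.0536). With slide as a block the medians were -0.19, 0.68, 0.11, 0.39 and -0.10 (adjusted p = 0.371, 0.0641, 0.609, 0.0752 and 0.866; within slide 1 0.403, 0.0890, 0.528, 0.0659 and 0.867).

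Of 19 homing genes 7 were higher, led by Itgae, Itgb7 (2.90), Cx3cr1 (at least 5.28-fold) and Cxcr4 (at least 3.60-fold), and 4 lower, Itga1 (at least 3.23-fold), Ccr2 (-1.07), Itgal (-0.69) and Itgb2 (-0.28; adjusted p = 0.0496), or 8 and 4 adjusted over the list alone. Itgal did not pass without ITNK 1 or ITNK 2 (adjusted p = 0.0713 for each). Itgb2 did not pass without any 1 of the LAK arrays, ITNK 1, ITNK 2, ITNK 4, DN3 2 or DN3 4 (adjusted p from 0.0574 to 0.132). The median of 0.34 passed (adjusted p = 0.0448; adjusted p = 0.247 with an estimated correlation), but not with slide as a block (0.22, adjusted p = 0.0932; within slide 1 0.124), without DN3 2 (0.34, adjusted p = 0.05), nor without ITNK 1, ITNK 2, ITNK 3 or ITNK 4 (0.15, 0.12, 0.15 and 0.04; adjusted p = 0.350, 0.421, 0.487 and 0.509).

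LAK and DN3 cells, the 2 reference populations, differed in more genes (4903) than ITNK and DN3 (4184), but with slide as a block in fewer (3322 against 3595). The blocked LAK against DN3 difference runs through the ITNK arrays of both slides and is less precise. Fewer calls there do not mean smaller differences, nor does the rise from 1617 to 1763 genes at least 2-fold different mean larger ones. The granzymes Gzmd and Gzme were higher in LAK by 7.71 (SE 0.71, adjusted p = 4.41e-07) and at least 104-fold, Klra7 by 7.04 (SE 0.24, adjusted p = 2.03e-11) and the inhibitory receptor Klre1 by 6.65 (SE 0.19). Zbtb32 was at least 113-fold higher. Pdlim4, a cytoskeletal LIM protein, was at least 333-fold lower, Myl10 fell by 6.90 (SE 0.20), Fam169b fell by 6.87, Arpp21 was at least 78.0-fold lower and Bgn at least 71.7-fold. Of 8100 genes 4903 passed, 2320 higher and 2583 lower in LAK, and 1617 differed at least 2-fold (790 higher, 827 lower). In the same 5 settings as for ITNK against DN3 that number was 990, 983, 936, 833 and 2596, and 8085 passed counting every probe. Groups did not overlap in 4568 genes (56.4%), against 2.86% by chance. The value of Gzmd was 10.08 with slide as a block, the largest move among the named genes.

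In LAK against DN3, 19 of 20 natural killer receptors were higher and Slamf6 (at least 4.81-fold) lower (median 3.08, or 3.06 with bounds, adjusted p = 1.72e-10), as were all 7 Ly49 genes (3.93, or 3.91 with bounds, adjusted p = 2.95e-07; adjusted p = 0.125 with an estimated correlation). Of 18 cytotoxic genes 16 were higher, such as Prf1 (4.45), 1, Lamp1 (-0.29), lower and Rab27a did not pass (median 2.23, adjusted p = 2.18e-07; adjusted p = 0.0642 with an estimated correlation). Of 19 T lineage surface genes 16 were lower, such as Cd8b1 (-5.75) and Cd3e (-5.49), Icos (1.73) and Cd28 (0.40) higher, and Zap70 did not pass (median -2.88, adjusted p = 2.63e-07; adjusted p = 0.0642 with an estimated correlation). Of 9 recombination genes 8 were lower and Slc6a13 (at least 1.56-fold) higher (median -2.11, adjusted p = 2.55e-04; adjusted p = 0.081 with an estimated correlation). Of 16 T lineage factors 11 were lower and 3, Hhex (at least 11.5-fold), Mef2c (at least 5.58-fold) and Ikzf3 (1.39), higher, while Foxo1 and Gfi1 did not pass (median -1.39, adjusted p = 0.00269; adjusted p = 0.203 with an estimated correlation). The call of Lamp1 was lost without LAK 2, LAK 4, DN3 1, DN3 3 or DN3 4 (adjusted p = 0.0959, 0.114, 0.0608, 0.110 and 0.0650). Lamp1, Cd28 and Slc6a13 did not pass with slide as a block (adjusted p = 0.317, 0.221 and 0.219). Gfi1 passed without LAK 3 (-0.42, adjusted p = 0.0155). All counts of these 6 lists were the same adjusted over the list alone. Their blocked medians were 3.64, 4.05, 2.51, -3.34, -2.37 and -1.59 (adjusted p = 6.69e-12, 5.67e-08, 1.08e-08, 1.34e-08, 1.7e-05 and 9.99e-04).

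Of 13 cytokines 10 were higher in LAK, such as Ccl4 (6.45), and Ccl9 (-1.46), Ltb (-1.12) and Il16 (-0.54) lower (median 1.31, adjusted p = 0.00125; adjusted p = 0.125 with an estimated correlation; 1.41 with slide as a block, adjusted p = 6.84e-04). Ccl9 did not pass with slide as a block (-1.11, adjusted p = 0.132). Of 8 Notch genes 5 were lower, such as Dtx1 (at least 16.5-fold), Nrarp (1.22) higher, and Maml1 and Myc did not pass (median -1.38, or -1.36 with bounds, adjusted p = 0.0345; adjusted p = 0.206 with an estimated correlation; -1.10 with slide as a block, adjusted p = 0.0487). The Notch list did not pass without DN3 1, DN3 2 or DN3 3 (adjusted p = 0.0972, 0.0956 and 0.0703). All 15 stromal markers were lower in LAK (-1.91, or -1.90 with bounds, adjusted p = 1.14e-06; adjusted p = 0.206 with an estimated correlation; -2.22 with slide as a block, adjusted p = 2.29e-06), as were all 3 gamma-delta and natural killer T cell genes (-5.18, adjusted p = 0.00125; adjusted p = 0.0642 with an estimated correlation; -5.58 with slide as a block, adjusted p = 4.12e-04). The calls of Fstl1, Timp3, Ccn2 and the Notch target Hes1 were lost with slide as a block (adjusted p = 0.0739, 0.213, 0.117 and 0.128). The natural killer factors (8 higher, 4 lower, median 0.70, adjusted p = 0.0897; 0.76 with slide as a block, adjusted p = 0.0700; 0.93 without LAK 3, where they passed, adjusted p = 0.0458), cytokine receptors (11 and 9, median 0.24, adjusted p = 0.543; -0.16 with slide as a block, adjusted p = 0.717) and homing genes (7 and 6, median 0.16, or 0.17 with bounds, adjusted p = 0.486; 0.08 with slide as a block, adjusted p = 0.428) did not pass. Counts adjusted over the list alone differed only for the natural killer factors (9 and 4). Of the myeloid genes Ctsg (at least 47.0-fold) and Cd14 (at least 2.93-fold) were higher in LAK and Csf1r and Lgmn (-0.59) lower, and of the mast cell genes Kit (1.41) and Cma1 (at least 1.87-fold) were higher and Cpa3 (-2.11) and Hdc (at least 1.55-fold) lower. Neither list passed (medians -0.04 and 0.13, means 1.252 and -0.11, adjusted p = 0.547 and 0.939; blocked medians -0.04 and 0.33, adjusted p = 0.604 and 0.898). The calls of Csf1r, Lgmn and Hdc were lost with slide as a block (adjusted p = 0.851, 0.0680 and 0.216), and that of Csf1r also without LAK 1, LAK 2, LAK 4, DN3 1 or DN3 3 (adjusted p = 0.0547, 0.0684, 0.0910, 0.0802 and 0.0996).

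Over the 3 comparisons 38 of 72 list tests passed, 36 of the 72 with slide as a block, and 6 of the 38 also with an estimated correlation. These 6 were the natural killer receptors, Ly49 genes, T lineage surface genes, recombination genes and gamma-delta and natural killer T cell genes in ITNK against LAK (adjusted p = 0.0452, 0.0452, 0.0363, 0.0363 and 0.0243), and the natural killer receptors in LAK against DN3 (adjusted p = 0.0451). By fry, which does not compare a list with other genes, 54 of the 72 passed. Under the slide block 160 of the 169 named genes that passed in ITNK against DN3 still passed in the same direction, as did 136 of 146 in ITNK against LAK and 169 of 202 in LAK against DN3.

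The 1617 genes at least 2-fold different between LAK and DN3 placed ITNK between the 2 populations. On a scale from 0 (DN3 mean) to 1 (LAK mean) the median position was 0.610 ± 0.0549 (SD, n = 4 ITNK arrays). It was 0.577 on slide 1, 0.642 on slide 2 and 0.683 over probes detected on every array. Genes higher in LAK had moved further (0.669 ± 0.0534, 790 genes) than genes lower in LAK (0.570 ± 0.0705, 827 genes), a difference that was not tested. Of the 1617 genes 281 (17.4%) lay under 0.25, 787 (48.7%) from 0.25 to 0.75, 492 (30.4%) above 0.75 but at most 0.25 beyond the LAK mean, and 57 (3.53%) further beyond it. By list, the median position was 0.660 for 19 natural killer receptors, 0.485 for 14 cytotoxic genes and 0.989 for 11 cytokines. It was 0.371 for 16 T lineage surface genes, 0.530 for 13 T lineage factors and 0.702 for 6 Notch genes. For 7 Ly49 genes, undetected in ITNK, -0.00829 was inexact. Stromal markers stood at 0.360 (13 genes). These genes were chosen by the LAK minus DN3 difference, which biases the value, and genes chosen on separate arrays gave 0.601 (1518 genes).

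**Figure D4:**
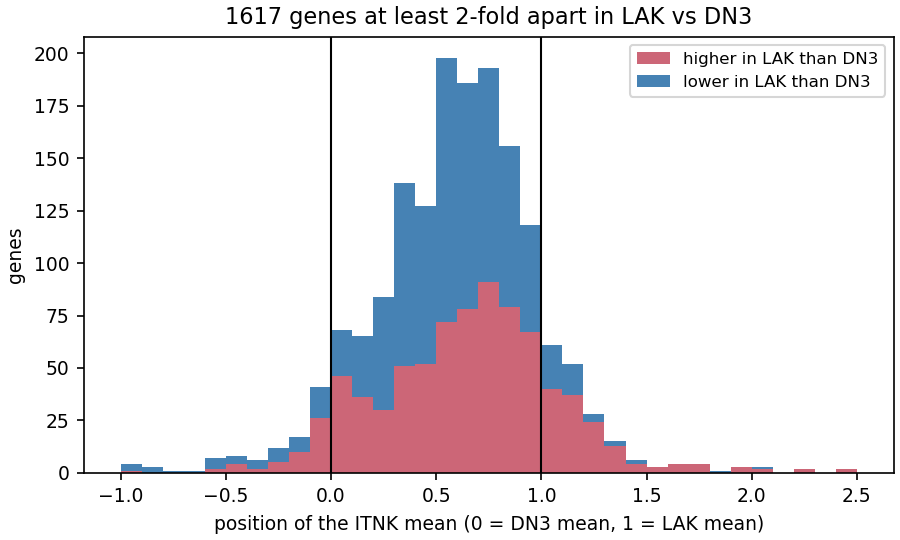
Histogram of the position of ITNK between DN3 (0) and LAK (1) for the 1617 genes at least 2-fold different between LAK and DN3 (x axis, position from group means; y axis, number of genes, stacked by whether they are higher or lower in LAK), with values outside the range drawn in the end bins. The counts peak between the DN3 and LAK means, where 787 genes lie from 0.25 to 0.75.

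A set of 139 genes lay outside the range of both other populations, at least 2-fold and past the test on both sides, 125 higher and 14 lower in ITNK. The set held 66 genes without background correction, with the fit to all probes or with the authors' values, and 57 with probes detected on all 12 arrays. Lta, the tumour necrosis factor relative lymphotoxin alpha, was at 9.81 ± 0.13 in ITNK against 5.33 ± 0.20 in DN3 and 6.05 ± 0.30 in LAK (SD, n = 4 each). B3gnt8, a glycosyltransferase, was higher by 4.21 than in DN3 and 4.26 than in LAK, the guanine nucleotide exchange factor relative Arfgef3 by 3.58 and 2.95, the homing receptor Gpr15 by 2.98 and 3.18 and the haemoglobin gene Hba-a1 by 2.91 and 3.52. Fxyd4, an ion pump regulator, was at least 12.2-fold and 13.6-fold higher, and the long noncoding RNA Miat at least 6.85-fold and 7.30-fold. Among the 14 lower genes, the repressor Gfi1 differed by -1.96 from DN3 and -1.67 from LAK, Pecam1 by -1.42 and -2.30, Myo6 by -1.60 and -2.12, Btbd11 by -1.80 and -1.54 and Adssl1 by -1.43 and -1.21.

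Both ITNK and LAK were compared with the same DN3 arrays, which alone makes their differences correlate. Across genes the covariance of ITNK minus DN3 with LAK minus DN3 was 0.650, against 0.0123 in simulated unchanged groups, so that the difference of 0.638 estimates the shared part on this scale. The covariance depended on the processing, from 0.286 with no filter to 0.761 with slide as a block. With different DN3 arrays in each comparison the covariance was 0.636 and 0.646. Of the 1903 genes higher in ITNK than in DN3, 1444 (75.9%) were also higher in LAK, and 1800 of the 2281 lower genes (78.9%) were also lower. Independent lists would share 545 and 727. The simulated groups shared 0 calls in either direction. Unchanged groups yield hardly any calls, so this cannot show how far shared controls raise the overlap. With the DN3 arrays split, 1017 and 1056 genes higher than DN3 were shared (independent lists 351 and 350.2) and 1291 and 1289 lower ones (458 and 451). In opposite directions went 82 of the genes higher in ITNK and 38 of the lower ones. Over all genes 81.5% of the 2 differences had the same sign, against 66.6% in the simulation.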

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

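The tests of a mixture, of the stromal transcripts and of the Bcl11b probes were chosen only after the result was seen, and the test of the slides and of other splits of the arrays before.

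Each ITNK array's median position lay between DN3 and LAK. Other groupings of the same arrays did not give as many genes past the test. Of the 35 splits of 8 arrays into 4 and 4 only 1, the real one, reached its count in each comparison. It gave 4215, 2447 and 4917 genes for ITNK against DN3, ITNK against LAK and LAK against DN3, with at most 4, 3 and 1 in any other split. Mixed splits add the group difference to the spread, which lowers their counts, and 1 of 35 is the smallest share possible. The result argues against chance for these arrays. It does not exclude a chance difference between single cultures, as arrays of a group may share one. A slide difference as the cause of the distance between LAK and DN3 is argued against by the blocked fit. With slide as a block 1763 genes were at least 2-fold different, against 1617 without. Even so, between the ITNK arrays of slide 2 and slide 1, 1 gene (Gpn2, 2.78) passed and 698 (8.62%) were at an unadjusted p under 0.05. The genes past the test dropped from 4903 to 3322 with the block, which also makes this difference less precise, and the cause of the drop was not tested. A mixture of unconverted DN3 cells with LAK-like cells is argued against as the whole account, since 139 of the 1055 genes at least 2-fold different between ITNK and DN3 (13.2%), Lta and B3gnt8 among them, lay outside the range of both. Fewer did in other settings (66 or 57, as given above). A population state of its own stays open as a hypothesis, as does a part of unconverted cells beside it, and differences in culture between the groups were not tested.

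Stromal transcripts were detected in DN3 and ITNK, and none of the 15 measured ones in LAK, while 12 of the 27 markers with a probe, such as Col1a2, Col3a1 and Dll1, did not pass the detection filter. The labels describe culture on OP9-DL1 stromal cells without saying for which groups, and carry-over of their RNA is a candidate source, which the sort described before that culture would not remove. A single source at a lower share in ITNK would keep the ratios between markers. Over all 15 their within-array spread was 4.54 times its standard error (4.11 over the 8 detected on all 8 arrays), above the bound of 2. The set of 15 holds Timp3 and Ccn2, which rose while no other marker did, and the set of 8 holds Ccn2. The ratio without them was not computed, so the argument against such a source as the whole account may rest on these 2. For the 10 markers that fell (median log2 ratio -1.86 of background-free signal, 27.5% left) the within-array spread was 1.82 times its standard error, between the bounds of 1.2 and 2. There such a source cannot be told apart from unequal change, although markers such as Serpinh1 (0.64, SE 0.12), Vcam1 (0.74, SE 0.22) and Sparc (-0.63, SE 0.22) departed from the others by more than 2 standard errors. These tests replaced a first one on the SD of the ratios (0.541, against a median standard error of 0.522) and 1 on Timp3 and Ccn2, which had been picked because they rose, and whether the unequal changes lay in lymphoid or stromal cells stays open.

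Bcl11b signal remained in ITNK at 10.8% of the DN3 signal by the brightest probe and at 43.2% and 38.9% by the 2 others detected. Undeleted cells as the only source are argued against, because they would leave the same share at each probe and the log2 ratios differed by 2.02 (SE 0.156). Binding of the 2 other probes to a transcript that all 3 cell types share is argued against by 0 detections of these probes on the LAK arrays, while a transcript absent from LAK stays open. A shortened Bcl11b transcript that keeps the part read by these 2 probes is a hypothesis that was not tested, as the place of each probe relative to the deleted part is not known here.

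Of 666 values of named genes tested within groups of 4, 31 (4.65%) had 1 array far from the other 3, where chance gives about 5%. LAK 3 held 8 of them. It was high in Aqp9 (10.95, others 9.97 to 10.07), Klrb1c (7.92, others 7.54 to 7.58), Mvk (6.73, others 6.03 to 6.10), Oasl2 (5.49, others 4.66 to 4.74) and Rpl12 (13.44, others 13.27 to 13.29). The same array was low in the cell cycle genes Cdk1 (9.17, others 9.89 to 9.92), Kif11 (7.31, others 7.99 to 8.13) and Mcm7 (6.87, others 7.96 to 7.97). LAK 1 was at 11.04 in Fdps (others 11.34 to 11.36), 7.02 in Il12rb2 (6.49 to 6.55), 6.67 in Pmvk (7.08 to 7.12) and 14.28 in Rps9 (14.12 to 14.15). LAK 2 was at 6.53 in Ifit2 (6.16 to 6.23), and LAK 4 at 5.73 in Itga1 (6.24 to 6.30) and 7.38 in Itgal (7.49 to 7.50).

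Among ITNK arrays, ITNK 1 was at 9.10 in Bcl11b (others 8.38 to 8.49) and 7.44 in Ets2 (7.21 to 7.24). ITNK 2 was at 9.59 in Rpl4 (9.66 to 9.67), 11.40 in Scin (11.50 to 11.51) and 5.199 in Slamf6 (4.92 to 4.96). ITNK 3 was at 5.04 in Btbd11 (4.58 to 4.59), 5.23 in Ccl9 (4.55 to 4.63), 9.18 in Ccn2 (8.34 to 8.39) and 5.50 in Oasl2 (6.28 to 6.40), and ITNK 4 at 7.10 in Otof (7.44 to 7.50). Among DN3 arrays, DN3 1 was at 5.30 in Zeb2 (4.74 to 4.76), and DN3 2 at 11.41 in Bcl11b (11.85 to 11.92) and 5.84 in Ikzf3 (4.99 to 5.05). DN3 3 was at 7.95 in Ccn2 (5.77 to 5.93), and DN3 4 at 4.95 in Hes1 (6.12 to 6.28) and 5.32 in Scin (6.75 to 6.99). Outside the gene counts, 86 of 1804 detected probes without a single gene symbol were at least 2-fold higher in ITNK than in DN3 and 123 lower.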

How the results depend on the processing

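No alternative was chosen after its result was seen. Over the alternatives the main results moved beyond their limits in 34 values and not in 331, none by changing sign. The values of named genes kept their direction and side of the threshold 18164 times, passed only in the alternative 206 times, lost the call 368 times and reversed 4 times, and list tests did so 1969, 51, 79 and 1 times. Of the genes at least 2-fold different, 1051 of 1055, 713 of 722 and 1567 of 1617 still passed in the same direction with slide as a block, 1045 within slide 2, 708 within slide 1, and 1055, 719 and 1617 with the authors' processed values. Named here in the order ITNK against DN3, ITNK against LAK and LAK against DN3, the genes at least 2-fold different numbered 561, 393 and 990 without background correction, 559, 388 and 983 with the fit to all probes, and 525, 378 and 936 with the authors' values, with 66 genes apart from both groups each time and covariances of 0.358, 0.357 and 0.346. The cause was not tested. With probes detected on all 12 arrays, fewer genes were tested: 537, 269 and 833 were at least 2-fold different, 1787 passed in ITNK against LAK, 57 lay apart, 20 lists passed, the median position was 0.683 and the covariance 0.445. The covariance was 0.286 with no filter, 0.567 with detection p under 0.05, 0.761 with slide as a block and 0.586 with the mean of probes, and the cause was not tested. Counting every probe gave 6745, 4307 and 8085 past the test, with 1646 and 2596 at least 2-fold in ITNK against DN3 and LAK against DN3, as more features were tested. The median position was 0.544 over genes at least 4-fold apart, and 6 lists passed with an estimated correlation. Hspa8 reversed in ITNK against DN3 with median scaling (0.00843) and with the mean of probes (0.16), and in LAK against DN3 with the mean of probes (0.51, adjusted p = 8.94e-04), Rpl32 in LAK against DN3 with slide as a block (-0.14), and the innate lymphoid list in LAK against DN3 was called lower by fry (median 0.34, adjusted p = 0.00181). The cause was not tested. With the mean of probes Id2 was lower in ITNK than in LAK (-0.41, adjusted p = 0.0115). The share of higher calls moved by under 10 percentage points in each setting, and no scaling moved the median of all genes by over 0.1.

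Without single arrays, Bcl11b stayed between -3.35 and -3.10, 2.65 and 2.90, and -6.14 and -5.82 in the 3 comparisons. The genes past the test numbered 3644 to 4373, 2280 to 2715 and 4477 to 4883, and those at least 2-fold different 975 to 1093, 653 to 726 and 1525 to 1619. Lists past the test numbered 33 to 40, genes apart 106 to 147, the median position was 0.589 to 0.634 and the covariance 0.632 to 0.682. With the replicate number as a block 4024, 2558 and 4771 genes passed. The numbers did not pair the arrays: correlations of same-numbered arrays ran from -0.339 to 0.209, and not every array matched its own number best. A value within 1 slide was not possible for LAK against DN3. As 26.1% to 29.0% of probes were detected per array, genes under the background have only bounds, and small differences of dim genes were not detectable.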

Other observations

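None of the list tests given here was chosen after its result was seen, and only single genes named as exceptions were. Interferon response genes were higher in ITNK than in either other population. Against DN3, 15 of 23 rose and Ifit2 fell by 0.86 (the same adjusted over the list alone; median 0.78, adjusted p = 6.98e-04; adjusted p = 0.214 with an estimated correlation; 0.71 with slide as a block, adjusted p = 0.00571; within slide 2 0.0033). Against LAK, 13 of the 23 were higher and 0 lower (15 and 0 adjusted over the list alone; median 0.50, adjusted p = 9.07e-06; adjusted p = 0.142 with an estimated correlation; 0.58 with slide as a block, adjusted p = 4.46e-06; within slide 1 1.3e-06). Between LAK and DN3 6 were higher and 7 lower in LAK (the same adjusted over the list alone; median -0.26, adjusted p = 0.938; -0.14 with slide as a block, adjusted p = 0.604). Ifit3, an antiviral effector, was higher in ITNK by 2.06 than in DN3 and by 2.05 than in LAK, the ubiquitin-like modifier Isg15 by 1.43 and 1.90 and the GTPase Gbp2 by 1.29 and 1.99.

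Genes of cholesterol synthesis were higher in ITNK and LAK than in DN3. In ITNK 12 of 16 rose, Dhcr7 fell by 0.69 and Idi1, Nsdhl (0.46; past without ITNK 2 or DN3 1, adjusted p = 0.0276 and 0.0367) and Srebf2 did not pass (the same adjusted over the list alone; median 0.66, adjusted p = 6.98e-04; adjusted p = 0.214 with an estimated correlation; 0.64 with slide as a block, adjusted p = 2.9e-04; within slide 2 4.36e-04), led by Cyp51 (1.61) and Mvk (1.14). In LAK 11 rose, Dhcr7 (-0.92) fell and Sqle (0.24; past with slide as a block, 0.55, adjusted p = 0.0195), Fdps, Idi1 and Srebf2 did not pass (the same adjusted over the list alone; median 0.64, adjusted p = 0.00379; adjusted p = 0.264 with an estimated correlation; 0.88 with slide as a block, adjusted p = 0.00142). Glycolysis genes were highest in LAK: 12 of 15 were higher than in DN3, Pfkm (-0.69) and Pdk1 (-0.62; not past without LAK 1, LAK 4, any 1 of the DN3 arrays, ITNK 1 or ITNK 4, adjusted p from 0.0518 to 0.162) lower and Hk1 did not pass (the same adjusted over the list alone; median 0.87, adjusted p = 0.00187; adjusted p = 0.336 with an estimated correlation; 0.98 with slide as a block, adjusted p = 0.0106). Of the 15, 8 were lower in ITNK than in LAK and 0 higher (9 and 0 adjusted over the list alone; median -0.61, adjusted p = 9.64e-05; adjusted p = 0.318 with an estimated correlation; -0.51 with slide as a block, adjusted p = 0.00103; within slide 1 9e-04). Among them were the glucose transporters Slc2a3 (-1.98) and Slc2a1 (-1.27), and the list median was -0.37 without LAK 3 and -0.38 without ITNK 3, with the call kept. Against DN3, 7 glycolysis genes rose in ITNK, such as Aldoc (1.79), and Pfkm (-1.01) and Pdk1 (-0.95) fell (the same adjusted over the list alone; median 0.46, adjusted p = 0.133; 0.64 with slide as a block, adjusted p = 0.239; within slide 2 0.121).

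Of 7 genes of MHC class II and antigen presentation 6 fell in ITNK against DN3 and H2-DMb1 did not pass (the same adjusted over the list alone; median -1.21, adjusted p = 0.00742; adjusted p = 0.285 with an estimated correlation; -1.42 with slide as a block, adjusted p = 0.0103; within slide 2 0.0151). H2-Eb1 was at least 4.80-fold lower, H2-Ob at least 4.62-fold and H2-Oa fell by 1.196. Cd74 (-1.21) did not pass with slide as a block (-0.89, adjusted p = 0.132). In LAK the same counts held against DN3 (the same adjusted over the list alone; median -2.06, adjusted p = 0.00365; adjusted p = 0.264 with an estimated correlation; -1.78 with slide as a block, adjusted p = 0.00878). There Cd74 and H2-Ab1 did not pass with slide as a block (adjusted p = 0.195 and 0.459), nor H2-Ab1 without LAK 1 (adjusted p = 0.0577). Against LAK, ITNK had H2-Oa (2.495) and H2-DMa (1.74) higher and H2-Ab1 (-1.29) lower, the last not without ITNK 1, ITNK 2, LAK 2, LAK 3 or LAK 4 (adjusted p = 0.0598, 0.0641, 0.0773, 0.0573 and 0.0505). Cd74 passed without DN3 3 (0.42, adjusted p = 0.0418). With all arrays H2-Eb1, H2-DMb1, H2-Ob and Cd74 did not pass there (the same adjusted over the list alone; median 0.19, or 0.34 with bounds, adjusted p = 0.260; 0.21 with slide as a block, adjusted p = 0.284; within slide 1 0.288).

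Of 19 p53 target and apoptosis genes 11 rose in ITNK against DN3 and Fas (-1.21) and Trp53inp1 (-0.77) fell (12 and 2 adjusted over the list alone; median 0.68, adjusted p = 0.0191; adjusted p = 0.214 with an estimated correlation; 0.69 with slide as a block, adjusted p = 0.0189; within slide 2 0.0133), with Cdkn1a, a cell cycle inhibitor, up by 1.93. Of 18 stress and immediate early genes 11 rose, Dnajb1 (-0.54) and Hspa8 (-0.27; 0.00843 with median scaling and 0.16 by the mean of its probes, adjusted p = 0.946 and 0.240; within slide 2 0.0650) fell and Jun, Dusp1, Hsph1 (past without ITNK 3, adjusted p = 0.0423), Ddit3 and Gadd45b did not pass (the same adjusted over the list alone; median 0.48, adjusted p = 0.0155; adjusted p = 0.214 with an estimated correlation; 0.54 with slide as a block, adjusted p = 0.0189; within slide 2 0.00589), with Fosl2 up by 2.88 and Egr3 by 2.13. In LAK against DN3 both lists passed (10 higher each, and 2 and 3 lower, the same adjusted over the list alone; medians 0.32 and 0.68, adjusted p = 0.0447 and 0.0352; adjusted p = 0.264 for both with an estimated correlation), but not with slide as a block (0.44 and 0.83, adjusted p = 0.0536 for both) nor without DN3 2 (adjusted p = 0.0849 and 0.0506), and the p53 list also not without DN3 3 (adjusted p = 0.0501). The lower genes were Fas (at least 11.9-fold) and Trp53inp1 (-2.55), and Gadd45a (-0.96), Dnajb1 (-0.85) and Fos (-0.71). In ITNK against LAK neither list passed (6 higher and 4 lower, or 7 and 5 adjusted over the list alone, median -0.01, adjusted p = 0.982; 3 higher and 3 lower, also adjusted over the list alone, median -0.15, adjusted p = 0.697; blocked medians -0.10 and -0.08, adjusted p = 0.846 and 0.649; within slide 1 0.867 and 0.613). There the survival genes Bcl2a1b (-3.85) and Bcl2a1d (-3.75) were lower, as were Bid (-0.47), Tnfrsf10b (-0.46), Ier3 (-1.10), Nr4a2 (-0.87) and Hsph1 (-0.44). Gadd45a (1.49), Fos (1.14) and Dnajb1 (0.31) were higher. Of these calls Tnfrsf10b lost its own with slide as a block (adjusted p = 0.0819). Hsph1 lost it without LAK 1, LAK 2, LAK 4, ITNK 2 or ITNK 4 (adjusted p from 0.0522 to 0.0808) and Dnajb1 without LAK 3, LAK 4, ITNK 1, ITNK 2 or ITNK 3 (adjusted p from 0.0590 to 0.0900).

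Of 29 cell cycle genes 8 fell and Ccnd2 (0.89) rose in ITNK against DN3 (5 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.288; -0.30 with slide as a block, adjusted p = 0.349; within slide 2 0.210), and 11 fell and Ccnd2 (0.63), Cdk1 (0.65) and Ccne1 (0.62) rose in LAK (9 and 3 adjusted over the list alone; median -0.30, adjusted p = 0.543; -0.28 with slide as a block, adjusted p = 0.667). With slide as a block Cdk1 and Ccne1 did not pass in LAK (adjusted p = 0.214 and 0.162). Between ITNK and LAK 0 of the 29 passed in limma, and 1 was at an unadjusted p under 0.05 (0 adjusted over the list alone; median -0.11, adjusted p = 0.770; -0.04 with slide as a block, adjusted p = 0.712; within slide 1 0.667), although the list passed without LAK 3 (-0.24, adjusted p = 0.0131), as did Cdk1 and Kif11 (adjusted p = 0.0390 for both). The other tests on these lists that did not pass were cholesterol synthesis in ITNK against LAK (Pmvk -0.39, others not past, and Pmvk itself not without LAK 2, LAK 3, LAK 4, ITNK 2 or ITNK 4, adjusted p from 0.0713 to 0.0967; median -0.04, mean 0.03, adjusted p = 0.982; -0.09 with slide as a block, adjusted p = 0.710; within slide 1 0.680) and the ribosomal proteins. In the cholesterol list Mvk passed without LAK 3, ITNK 1, ITNK 3 or DN3 3 (adjusted p from 0.00977 to 0.0459), Cyp51 and Idi1 without ITNK 2 (adjusted p = 0.0281 and 0.0312) and Hsd17b7 without LAK 1, LAK 4, ITNK 2 or DN3 2 (adjusted p from 0.0135 to 0.0499). Of 16 ribosomal genes Rpl22 (-0.66), Rps9 (-0.28), Rpl3 (-0.26) and Rps14 (-0.25) fell against DN3 (1 adjusted over the list alone; median -0.04, adjusted p = 0.673; -0.14 with slide as a block, adjusted p = 0.349; within slide 2 0.354), and Rpl4 (-0.24) was lower than in LAK (0 adjusted over the list alone; median -0.08, adjusted p = 0.412; -0.05 with slide as a block, adjusted p = 0.649; within slide 1 0.667). In LAK against DN3 Rpl4 (0.31) and Rpl32 (0.30) were higher and Rpl22 (-0.83), Rps14 (-0.39) and Rps9 (-0.25) lower (1 and 2 adjusted over the list alone; median 0.07, mean -0.01, adjusted p = 0.872; -0.08 with slide as a block, adjusted p = 0.717). Several of these ribosomal calls were lost in other fits. Slide as a block ended those of Rpl3 and Rps9 against DN3 (adjusted p = 0.0704 and 0.123), of Rpl4 in both LAK comparisons (adjusted p = 0.0795 and 0.0728) and of Rps9 between LAK and DN3 (adjusted p = 0.669), and reversed Rpl32 (-0.14, adjusted p = 0.470). In ITNK against DN3, Rpl3 did not pass without DN3 3 or DN3 4 (adjusted p = 0.0550 and 0.0555) and Rps14 without ITNK 3, ITNK 4, DN3 2, DN3 3 or DN3 4 (adjusted p from 0.0508 to 0.0875). Rpl4 did not pass against LAK without any 1 array except LAK 3 and DN3 2 (adjusted p from 0.0521 to 0.1202). In LAK against DN3, Rps9 did not pass without LAK 2, LAK 4, DN3 1 or DN3 2 (adjusted p from 0.0506 to 0.0597). Rpl3 passed there without LAK 3 (-0.24, adjusted p = 0.0317), and Rpl12 and Rpl32 passed in ITNK against LAK without ITNK 1 (-0.37 and -0.35, adjusted p = 0.0267 and 0.0454). In LAK against DN3 Rpl32 did not pass without any 1 of the LAK arrays or DN3 1, DN3 2 or DN3 4 (adjusted p from 0.0671 to 0.111).

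Of 8 genes of other innate lymphoid types Kit (1.44) and Ltb4r1 (at least 6.13-fold) rose and Il7r (-2.30), Il17rb (-2.11) and Gata3 (-0.79) fell in ITNK against DN3, while Tmem176a, Tmem176b and Klrg1 did not pass (the same adjusted over the list alone; median 0.18, mean -0.05, adjusted p = 0.778; -0.01 with slide as a block, adjusted p = 0.619; within slide 2 0.760). Against LAK, Il17rb (at least 3.61-fold), Il7r (1.17) and Gata3 (0.88) were higher and Klrg1 (-4.87) and Ltb4r1 (-2.86) lower, while Kit, Tmem176a and Tmem176b did not pass (the same adjusted over the list alone; median -0.02, mean -0.51, adjusted p = 0.895; 0.15 with slide as a block, adjusted p = 0.649; within slide 1 0.667). In LAK against DN3 Ltb4r1 (at least 44.5-fold), Klrg1 (at least 34.96-fold) and Kit (1.41) were higher and Il17rb (at least 15.6-fold), Il7r (-3.46) and Gata3 (-1.67) lower (the same adjusted over the list alone; median 0.34, adjusted p = 0.939; -0.04 with slide as a block, adjusted p = 0.717).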
